A study of Arabidopsis thaliana with 12 samples.

How the data were processed

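RNA was measured in whole rosettes, without roots, of 25-day-old *Arabidopsis thaliana* plants grown in soil at 20 °C under 16 h light and 8 h dark, per the labels' protocols. The 4 genotypes (Col-0, cdk8-1, jazD and jazD cdk8-1) had 3 replicates each, every one a pool of about 10 plants, and the genotypes shared a tray, per the labels' protocols. Libraries were made with a BGI transcriptome kit and sequenced on a DNBseq platform, and RNA integrity scores were at least 6.5, per the labels' protocols. The hour of harvest, the read length, the strand protocol and the aligner are not given in the sources used here.

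Expected counts per gene were made by the authors with RSEM 1.2.25 against TAIR10, per the submitters' processing notes. TPM values per gene were made by the authors with the same tool, per the submitters' processing notes, and were used here only as an alternative scaling. Each table held 33323 loci in 12 libraries. Of the expected counts, 96.58% were whole numbers, and all were rounded to whole numbers before testing. In all libraries 8990 loci were at 0. Names came from a TAIR10.1 annotation table, which matched 32835 of the 33323 loci by locus identifier. No coordinates are printed, since that build and the authors' build carry different names, and only the order of genes along the chromosomes was used.

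Counts were tested with edgeR 4.0.16 in R 4.3.3. Loci were filtered with filterByExpr, which left 19059, and library sizes were scaled by TMM, with factors from 0.9543 to 1.0557. One quasi-likelihood model with a mean per genotype was fitted to all 12 libraries (8 residual degrees of freedom), and the common biological coefficient of variation was 5.1%. Comparisons of pairs of genotypes and the interaction, which is the *cdk8-1* effect in jazD minus that with intact *JAZ* genes, were tested 2-sided. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested, with no fold threshold. Log2 fold changes carry an approximate standard error, which is the size of the fold divided by the square root of its quasi-likelihood F statistic. For genes with few counts it can lie below the error from counting alone. CPM levels carry the SD of 3 pools. Near-identical genes such as the *PDF1.2* copies, *AOC1* and *AOC2*, and overlapping genes depend on how the authors' tool divided reads among them.

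Lists of genes were fixed with the tests and the rule for naming genes before the data were examined. They hold 365 genes in 28 lists, of which 25 had enough genes tested to be treated as sets. In the lists, 9 genes were left out because the reference table gives their locus another name. Lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over all lists and comparisons. The same test with an estimated correlation and the rotation test fry were alternatives. List calls numbered 77 with the preset correlation, 38 with the estimated correlation and 104 with fry. Counts of list members adjusted over the list alone used the same p-values. The lists of floral, root, senescence, heat shock, touch and clock genes served as markers of other organs or states.

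Genes are named by a rule fixed in advance. For jazD against Col-0, cdk8-1 against Col-0, jazD cdk8-1 against jazD and the interaction, it takes the 5 largest rises and 5 largest falls among called genes with an average log2 CPM of at least 1, without overlap between libraries except for the interaction. It adds *CDK8* and the *JAZ* genes, and from each list up to 4 members with the smallest adjusted p. Other named genes were chosen after their values were seen: *PDF1.2a*, genes of the chromosome 5 interval beyond the largest changes, AT5G32950, AT4G08093 and members of the lectin family. Where a group had 0 counts the fold is a lower bound with 3 counts in that group, and where it had 1 to 3 counts the ratio is given with a 95% interval from counting error alone.

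The counts of genes called in pairs of comparisons were set beside the number from independent lists and beside 20 simulated data sets without an effect of *cdk8-1* in jazD. The slope of the jazD effect without CDK8 on that with CDK8 passed through the origin and was compared with simulations of equal effects. The interval on chromosome 5 was sought after the values were seen, by counting genes at least 8-fold lower in windows of 1000 tested genes and shuffling gene order 10000 times. Levels in jazD cdk8-1 were classed as near Col-0 (within 2-fold), near jazD (within 2-fold or no called change) or between, and runs of these along the interval were compared with shuffled orders. Runs were also counted with each gene given to the nearer of Col-0 and jazD, a rule likewise chosen after the values were seen.

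The tests of single genes between pairs of genotypes, camera and the slope were tested on simulated data. In a simulation of jazD against Col-0 over 18753 genes, edgeR called 52 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 11 of 18553 unchanged genes. The 200 changed genes were drawn only from genes above a minimum level in Col-0, so recovery of genes at lower levels was not tested. They are also far fewer than the genes called in the real data. camera called the planted list and 0 of 20 random lists. A true slope of 0.5 was returned as 0.481 over 7089 genes. DESeq2 1.42.0 and limma served as alternatives to edgeR.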

Results

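RNA sequencing measured gene expression in rosettes of 25-day-old *Arabidopsis thaliana* plants of 4 genotypes, with 3 libraries per genotype. Each library came from a pool of about 10 plants, so a replicate is a pool and not a single plant. Col-0 is the wild type. The jazD line carries mutations in 10 genes for JAZ proteins (*JAZ1* to *JAZ7*, *JAZ9*, *JAZ10* and *JAZ13*), which repress jasmonate-responsive transcription. The *cdk8-1* line carries a mutation in *CDK8*, the gene of the cyclin-dependent kinase that associates with the Mediator complex. The fourth genotype, jazD cdk8-1, combines all of these mutations. Total counts per library were 19670772, 19957293 and 20407951 in Col-0, 18994055, 19051879 and 19980184 in cdk8-1, 19250698, 20863055 and 17583467 in jazD, and 17894260, 20740605 and 21030374 in jazD cdk8-1. Of 33323 loci, 19059 had enough counts to be tested. By its title, the series addresses the part that CDK8 plays in the defence gene expression of jazD. Levels are given as CPM (mean ± SD, n = 3), and changes as log2 fold changes ± an approximate standard error. That error was derived from the fold and its F statistic in an edgeR quasi-likelihood fit to all 12 libraries. It can be too small for genes with few counts. Genes of a list were counted after adjustment over all genes tested. Counts adjusted over the list alone stand beside them where they differ and are otherwise the same. Genes with the largest changes were taken from called genes with an average log2 CPM of at least 1, and, except for the interaction, no overlap between the libraries compared, so genes of lower abundance can have larger folds.

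The targeted gene was examined in each library first. *CDK8* had 335, 370 and 406 counts in the Col-0 libraries and 388, 409 and 339 in the jazD libraries, against 46, 53 and 55 in cdk8-1 and 49, 69 and 71 in jazD cdk8-1. Its level fell 7.31-fold in cdk8-1 relative to Col-0 (−2.87 ± 0.10) and 6.54-fold in jazD cdk8-1 relative to jazD (−2.71 ± 0.10). Between jazD and Col-0 the change was 0.12 ± 0.08 (adjusted p = 0.202, edgeR), and the 4 genotypes matched their labels at this gene.

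Of the mutated *JAZ* genes, 9 had enough counts to be tested, and their transcripts were affected unequally in jazD. *JAZ1* (−2.26 ± 0.15), *JAZ2* (−3.03 ± 0.11) and *JAZ6* (−3.47 ± 0.11) fell the most, and *JAZ4* (−1.47 ± 0.49) and *JAZ3* (−0.20 ± 0.06) fell as well. *JAZ10* (2.17 ± 0.18), *JAZ13* (4.01 ± 0.49) and *JAZ9* (0.17 ± 0.05) rose, and *JAZ5* changed by −0.29 ± 0.23 (adjusted p = 0.332, edgeR). *JAZ7* was at the limit of detection, with 5, 1 and 0 counts in the Col-0 libraries and 0, 0 and 1 in those of jazD, so no fold is given. Of the 3 intact genes, *JAZ8* rose from 0.153 ± 0.136 to 3.09 ± 0.463 CPM (4.29 ± 0.40), *JAZ12* rose by 0.33 ± 0.06, and *JAZ11* changed by 0.04 ± 0.10 (adjusted p = 0.81, edgeR). The calls of *JAZ3*, *JAZ4* and *JAZ9* did not hold when certain single libraries were left out. Without Col-0 replicate 1 the change of *JAZ3* was −0.18 (adjusted p = 0.0516, edgeR) and without jazD replicate 2 it was −0.14 (adjusted p = 0.104, edgeR). *JAZ4* gave −1.32 without Col-0 replicate 2 (adjusted p = 0.0701, edgeR) and −1.17 without jazD replicate 3 (adjusted p = 0.0807, edgeR), and *JAZ9* gave 0.13 without Col-0 replicate 3 (adjusted p = 0.0713, edgeR). The *JAZ9* call was also lost in the 3 tests on TPM values. As a list, the mutated *JAZ* genes had 3 higher and 5 lower, with an adjusted p of 0.00239 with the preset correlation and an adjusted p of 0.0653 with an estimated correlation.

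**Figure D1:**
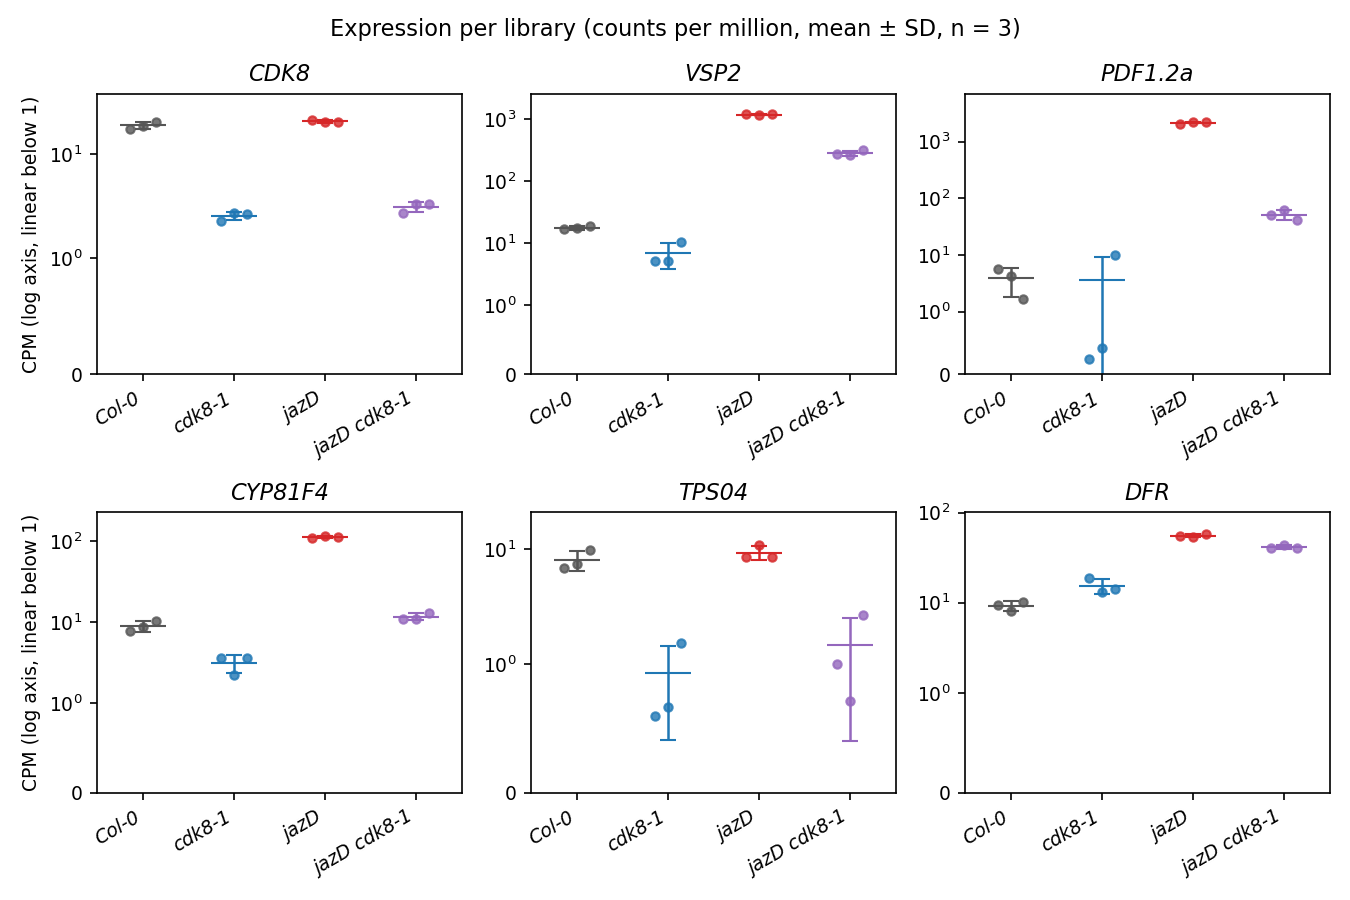
CPM in each library (points) for *CDK8*, *VSP2*, *PDF1.2a*, *CYP81F4*, *TPS04* and *DFR* in the 4 genotypes, with the mean and SD (n = 3) on a log axis that is linear below 1. *CDK8* means lie at 18.8 and 20.4 CPM in Col-0 and jazD and at 2.56 and 3.11 CPM in cdk8-1 and jazD cdk8-1, while *VSP2* reaches 1169 CPM in jazD and 280.3 CPM in jazD cdk8-1.

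The comparison of jazD with Col-0 asks what the loss of the JAZ repressors changes in plants with CDK8. Genes of anti-insect defence rose far. *VSP2*, a vegetative storage protein gene induced by jasmonate, rose 66.3-fold from 17.7 ± 1.09 to 1169 ± 28.3 CPM (6.05 ± 0.12). *MBP1*, which encodes a myrosinase-binding protein (5.03 ± 0.08), *JAL35*, a jacalin-related lectin gene (3.45 ± 0.06), and *ARGAH2*, an arginase gene (2.64 ± 0.04), rose as well. Of 18 such genes tested, 13 were higher and 1 was lower, with a median of 2.70 and an adjusted p of 0.000498 with an estimated correlation. The branch controlled by jasmonate and ethylene together rose in full, with 14 of 14 genes higher and a median of 4.26 (adjusted p = 0.00798 with an estimated correlation). *ORA59*, the transcription factor gene of that branch, rose 47.2-fold to 52.7 ± 4.50 CPM, *PR4* rose to 1746 ± 81.7 CPM (5.57 ± 0.15), and the basic chitinase gene *CHIB* rose by 3.77 ± 0.12. The defensin genes *PDF1.3* (10.86 ± 0.49), *PDF1.2c* (10.28 ± 0.32) and *PDF1.2b* (9.41 ± 0.27) were among the 5 largest rises by that rule. They are close copies of each other and of *PDF1.2a*, so the split of reads among them is uncertain, and *PDF1.2a* (2179 ± 76.6 CPM in jazD) was picked after its values were seen.

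Jasmonate synthesis and turnover rose together in jazD. *LOX2*, the lipoxygenase gene of the first step, went from 564.7 ± 8.17 to 4825 ± 119 CPM (3.09 ± 0.05), the allene oxide cyclase genes *AOC1* (3.24 ± 0.06) and *AOC2* (2.78 ± 0.05) rose, and *AOS*, the allene oxide synthase gene, rose by 1.95 ± 0.05. Of 15 synthesis genes tested, 13 were higher and 1 lower, with a median of 1.28 and an adjusted p of 3.51e-05 with an estimated correlation. In signalling and catabolism, 14 of 17 genes were higher and 1 lower (median 1.00, adjusted p = 0.00275 with an estimated correlation). There *JAO2*, a jasmonate oxidase gene, rose 18.6-fold (4.22 ± 0.07), *MYC2*, the gene of the main transcription factor bound by JAZ proteins, rose by 1.71 ± 0.07, and the amidohydrolase genes *ILL6* (2.05 ± 0.08) and *IAR3* (1.14 ± 0.06) rose.

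Among defence metabolites, the indole and aliphatic glucosinolate pathways moved in opposite directions in jazD. For indole glucosinolates, 15 of 18 genes were higher and 3 lower, with a median of 1.04 (adjusted p = 0.00093 with an estimated correlation). *CYP81F4*, which modifies the indole ring, rose 12.6-fold to 111.9 ± 3.73 CPM, *IGMT5*, a methyltransferase gene, rose by 4.36 ± 0.11, and *CYP79B3*, which starts the pathway from tryptophan, rose by 1.99 ± 0.06. Tryptophan synthesis supplies that pathway, and 8 of its 9 genes were higher (8 higher and 1 lower adjusted over the list alone, median 1.15, adjusted p = 0.00473 with an estimated correlation). *PAT1* (1.59 ± 0.05), *TSA1* (1.63 ± 0.06) and *TSB1* (1.74 ± 0.05) were examples, of which *TSB1* lies in the chromosome 5 interval described below. For aliphatic glucosinolates, 16 of 18 genes were lower, with a median of −0.50 (adjusted p = 8.36e-09 with the preset correlation and adjusted p = 0.134 with an estimated correlation). *CYP79F1*, the entry enzyme from methionine, fell from 347 ± 13.5 to 215.3 ± 18.7 CPM (−0.69 ± 0.05), and *FMOGS-OX3* fell by 0.80 ± 0.05 on the log2 scale.

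Enzymes and structures that act on glucosinolates were also higher in jazD. Of 11 genes for myrosinases, specifier proteins and ER bodies, 9 were higher and 1 lower, with a median of 0.80 (adjusted p = 1.56e-05 with an estimated correlation). *BGLU18*, a beta-glucosidase gene of inducible ER bodies, reached 7514 ± 86.7 CPM from 437.7 ± 26.9, a 17.1-fold change, *NAI2*, needed to form ER bodies, rose by 3.68 ± 0.07, and *PYK10*, best known from roots, rose by 3.20 ± 0.08. Flavonoid and anthocyanin genes rose, with 14 of 19 higher and 1 lower (14 and 2 adjusted over the list alone, median 1.09, adjusted p = 0.00269 with an estimated correlation). *LDOX* (2.87 ± 0.09), *DFR* (2.58 ± 0.10) and *UGT75C1* (1.90 ± 0.08), which act late in anthocyanin synthesis, rose more than the entry enzyme gene *CHS* (1.09 ± 0.05). All 4 camalexin genes were higher, such as *PAD3* (2.53 ± 0.30), which makes camalexin itself (median 2.15, adjusted p = 0.0406 with the preset correlation and adjusted p = 0.464 with an estimated correlation). Among phenylpropanoid and hydroxycinnamate amide genes, 6 of 18 were higher and 5 lower (adjusted p = 0.0277 with the preset correlation and adjusted p = 0.156 with an estimated correlation). There *DTX18*, a transporter gene, rose 64.0-fold to 243.9 ± 10.8 CPM, while the lignin gene *HCT*, which lies in the chromosome 5 interval, fell by 0.57 ± 0.04 on the log2 scale.

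Growth and photosynthesis genes changed by less. Of 27 photosynthesis genes, 17 were lower and none higher (18 lower adjusted over the list alone, median −0.15, adjusted p = 0.000284 with the preset correlation and adjusted p = 0.581 with an estimated correlation). *RCA*, the Rubisco activase gene, fell from 8680 ± 189 to 5320 ± 222 CPM (−0.71 ± 0.05), and *GAPB* fell by 0.48 ± 0.04 on the log2 scale. Of 19 genes for cell expansion and growth hormones, 11 were lower and 1 higher (12 and 2 adjusted over the list alone, median −0.38), with the expansin genes *EXPA11* (−1.52 ± 0.07) and *EXPA8* (−1.15 ± 0.06) as examples (adjusted p = 0.00239 with the preset correlation and adjusted p = 0.356 with an estimated correlation). In the cell cycle list, 10 of 21 genes were lower (median −0.19), including *CDKB2;2* (−0.58 ± 0.10), but the list test did not pass (adjusted p = 0.09 with the preset correlation). Senescence genes were higher in 9 of 11 cases (median 0.59, adjusted p = 0.00243 with the preset correlation and adjusted p = 0.23 with an estimated correlation), with *FRK1* (3.62 ± 0.38) and the chlorophyll breakdown gene *PPH* (0.74 ± 0.05) among them.

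Several further lists described the state of the plants, and markers of other organs were nearly absent. Of 18 salicylate defence genes, 7 were higher and 2 lower in jazD (median 0.23, adjusted p = 0.352 with the preset correlation), with *PR5* (1.95 ± 0.19) and *EDS5* (1.26 ± 0.15) among the higher ones. Touch and general stress genes were higher in 6 of 7 cases, such as *ZAT10* (1.99 ± 0.18) and *TCH3* (1.06 ± 0.11), with a median of 1.16 (adjusted p = 0.0326 with the preset correlation and adjusted p = 0.452 with an estimated correlation). Clock genes were split, with 5 of 9 higher and 4 lower: the morning genes *CCA1* (−1.58 ± 0.07) and *PRR9* (−1.77 ± 0.07) fell, and the evening genes *LUX* (1.57 ± 0.08) and *TOC1* (1.11 ± 0.07) rose. The hour of harvest is not given, so a difference in hour between genotypes could add to these and to other calls. Heat shock genes gave 1 higher of 4 and none adjusted over the list alone, cuticle genes 5 higher and 4 lower of 10 (median 0.20, mean −0.13), flowering time genes 1 higher (*MAF5*, 2.07 ± 0.20) and 2 lower of 6, and reference genes 1 higher of 6 (*ACT2*, 0.18 ± 0.05, a call lost in the 3 tests on TPM values). Of the 11 other Mediator subunits, 2 were higher and 1 lower (1 higher and none lower adjusted over the list alone). Only 1 of 8 floral markers and 1 of 9 root markers had enough counts to be tested. The floral gene *AG* was lower in jazD, at 0.256 ± 0.153 CPM against 0.708 ± 0.0886 (−1.47 ± 0.45, and −1.12 with adjusted p = 0.0712 by edgeR without jazD replicate 1), and the root nitrate transporter gene *NRT2.1* was higher, at 2.48 ± 0.389 against 0.554 ± 0.325 CPM.

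Over all genes, 4162 were higher and 3991 lower in jazD than in Col-0, or 42.8% of those tested, and 817 and 435 of them changed at least 2-fold. The groups of 3 libraries did not overlap for 51.5% of the genes tested, against 10% by chance. Of the called genes, 51.0% were higher, against 37.9% when the deposited TPM values were tested on the log2 scale, and no gene called in both changed direction. AT5G28810, a gene with a domain of unknown function, had 0 counts in Col-0 and 1682 in jazD, at least 597-fold higher. Its rise was the largest by the fitted fold alone, which has no upper bound at 0 counts. *AACT1* (AT5G61160), an acyltransferase gene, rose by 9.59 ± 0.29. It was planned for the phenylpropanoid and hydroxycinnamate amide list and was left out of it because its locus has another name.

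By the fitted fold, which has no bound for genes at 0 counts, the 5 largest falls in jazD were those of AT5G50565 (0 counts in jazD, at least 155-fold lower), AT4G12917 (0 counts, at least 89.5-fold lower), AT5G49440 (−9.49 ± 0.21), AT5G45490 (−9.42 ± 0.20) and AT5G49640. The last of these had 1 count in jazD, which gives a ratio of 403 (95% counting interval 71.9 to 15900). AT5G49440 and AT5G45490 had 6 and 5 summed counts in jazD (0.118 ± 0.205 and 0.0987 ± 0.171 CPM). Their folds are thus less certain than the standard errors show. All of the 5 genes except AT4G12917 lie on chromosome 5, which led to a scan along the chromosomes after the values had been seen. Of 38 genes at least 8-fold lower in jazD, 23 lay between AT5G44490 and AT5G56910, an interval that holds 926 of the genes tested (4.9%). In 10000 shuffles of the gene order, no more than 11 such genes fell in any window of 1000 genes (one-sided permutation p = 1e-04, the smallest these shuffles can give). The median change of the 23 genes in cdk8-1 relative to Col-0 was 0.01. None of the mutated *JAZ* genes and 13 list genes lie in the interval, namely *MYC3*, *ERF5*, *TSB1*, *NSP5*, *UGT79B1*, *MYB111*, *HCT*, *COMT1*, *LHCB3*, *MCM3*, *CYCC1;1*, *CYCC1;2* and *HSP90.1*. *PDF1.2a* and *PDF1.2c* lie just before its first gene, and *CDK8* lies farther along the same chromosome.

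In jazD cdk8-1, the level of a gene was taken as near Col-0 within 2-fold of it, as near jazD within 2-fold of it or with no called change, and as between otherwise. At 15 of the 23 genes, such as AT5G45490 (66.1 ± 3.5 CPM in Col-0, 0.0987 ± 0.171 in jazD and 56.3 ± 1.80 in jazD cdk8-1), the level was near that of Col-0. At the 5 genes of the first stretch (AT5G44490, AT5G44530, AT5G44569, AT5G44580 and AT5G44582), the level was between those of Col-0 and jazD, as for AT5G44530 (86.0 ± 3.21, 10.5 ± 0.953 and 29.1 ± 2.68 CPM in the same order). By that rule it was near jazD at 3 genes, which were *AtPP2-A6*, *TRM24* and AT5G52940. *AtPP2-A6* had no called change from jazD, with 0 counts in jazD and 5 in jazD cdk8-1. Its rise from jazD was at least 1.53-fold (log2 0.62), with a fitted value of 3.80, and its change against Col-0 was −2.71. Whether it was nearer Col-0 or jazD is thus not settled. These levels formed 6 runs along the interval, against a median of 13 in shuffled orders (one-sided permutation p = 4e-04). With each gene given to the nearer of Col-0 and jazD, 20 and 3 genes formed 5 runs, against a median of 7 (one-sided permutation p = 0.261). This second rule gave AT5G44530 to jazD on a near tie (−1.56 against Col-0 and 1.48 against jazD) and *AtPP2-A6* to Col-0 by its fitted value. Its runs rest in part on these genes, so its p does not decide whether levels are ordered along the interval. The first rule also placed *AtPP2-A6* on the same few counts, so its p rests in part on an unsettled level. The 5 genes of the first stretch lay at −1.38 to −1.56 against Col-0. Genes of the interval named in this paragraph were chosen after their values were seen.

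**Figure D2:**
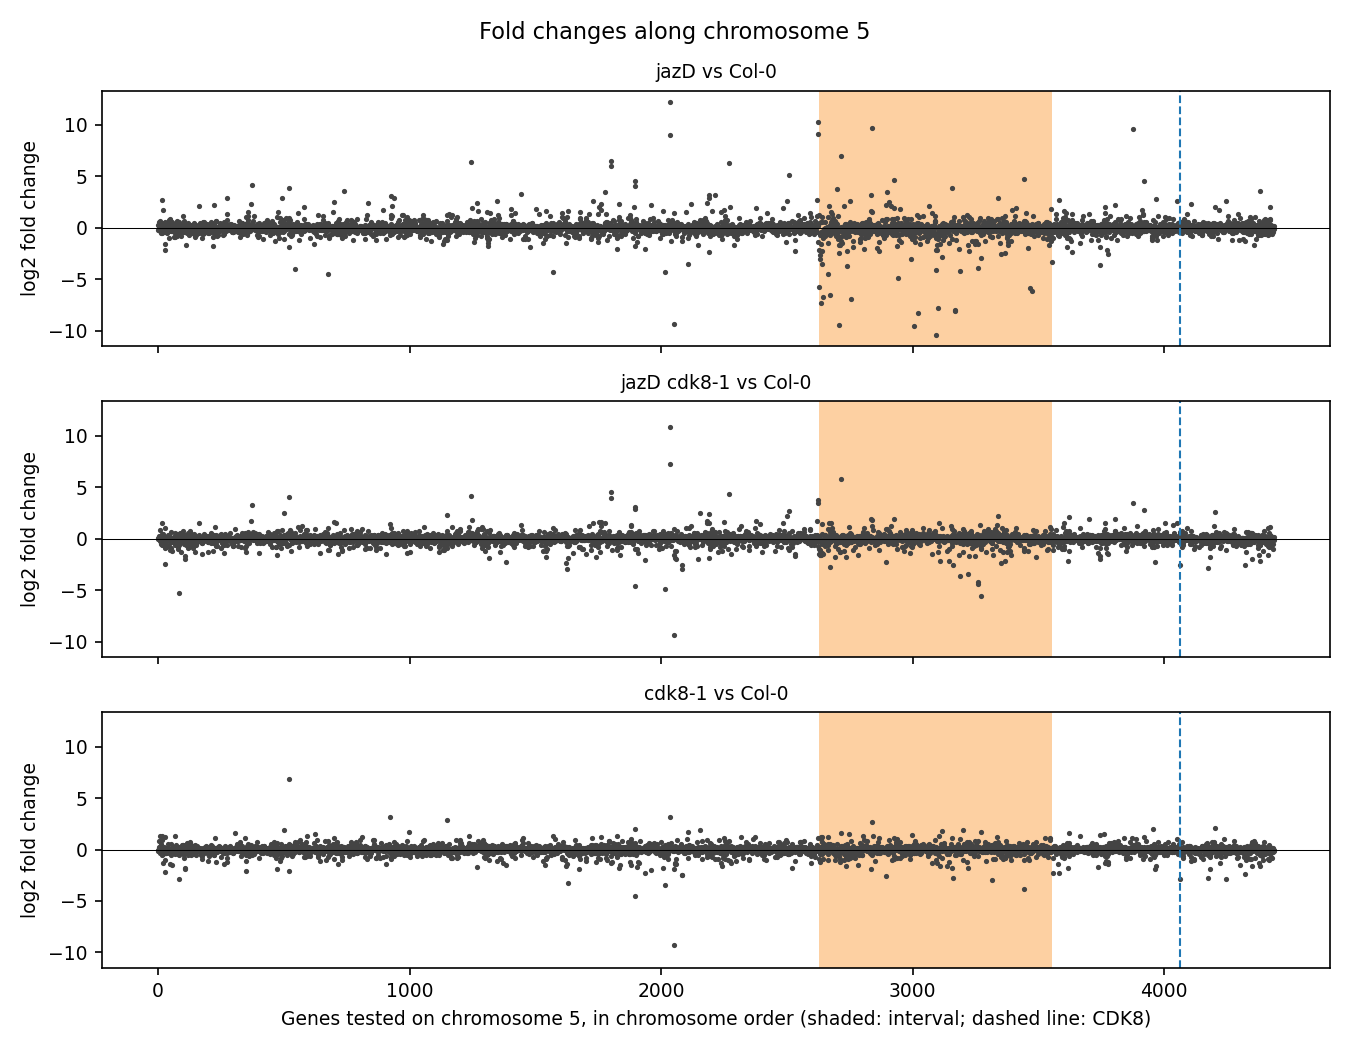
Log2 fold change of each gene tested on chromosome 5, in chromosome order, for jazD, jazD cdk8-1 and cdk8-1 against Col-0 (1 point per gene, 3 libraries per genotype). The shaded interval holds 23 of the 38 genes that are at least 8-fold lower in jazD, 15 of these 23 are near the Col-0 level in jazD cdk8-1, and the dashed line marks *CDK8*.

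The comparison of cdk8-1 with Col-0 asks what CDK8 does in plants that have the JAZ repressors. Genes of volatile and anti-insect defence fell. *TPS04*, which encodes the geranyllinalool synthase of leaf volatiles, fell 8.46-fold from 8.01 ± 1.53 to 0.936 ± 0.522 CPM (−3.08 ± 0.31), and *CYP82G1*, which acts after it in the same pathway, fell by 4.98 ± 0.46 on the log2 scale. The terpene synthase gene *TPS03* (−2.66 ± 0.25) and the myrosinase-binding protein gene *MBP2* (−2.24 ± 0.12) fell as well. Of the 18 anti-insect genes, 11 were lower and none higher (12 lower adjusted over the list alone, median −0.58, adjusted p = 0.0295 with an estimated correlation). Flavonoid genes moved the other way, with 12 of 19 higher and 1 lower (median 0.65, adjusted p = 0.00275 with an estimated correlation). *FLS1*, the flavonol synthase gene, rose from 18.6 ± 0.533 to 53.2 ± 2.90 CPM, and *F3H* (0.93 ± 0.08), *CHI* (0.85 ± 0.08) and *CHS* (0.84 ± 0.05) rose too.

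Further groups were lower in cdk8-1 by counts of genes, without a list call that held with an estimated correlation. Of 18 salicylate defence genes, 10 were lower (12 adjusted over the list alone, median −0.72, adjusted p = 0.000903 with the preset correlation and adjusted p = 0.487 with an estimated correlation). *ALD1* (−2.97 ± 0.41) and *PR1* (−2.06 ± 0.47), of systemic resistance, and *EDS5* (−1.16 ± 0.19), of salicylate export, were among them. The *PR1* call was lost in the test on TPM values without a filter. In the jasmonate and ethylene branch, 5 of 14 genes were lower, such as *PR4* (−1.67 ± 0.17) and *ERF6* (−1.79 ± 0.24), with an adjusted p of 0.00395 with the preset correlation and an adjusted p of 0.277 with an estimated correlation. The cdk8-1 libraries differed among themselves in this branch, with *PDF1.2a* at 10.2 CPM in replicate 3 and at 0.249 and 0.414 CPM in the others, and *VSP2* was at 10.4 CPM in replicate 3 against 5.09 and 5.22 CPM. Of 18 indole glucosinolate genes, 8 were lower and 4 higher (9 and 5 adjusted over the list alone, median −0.23, adjusted p = 0.00494 with the preset correlation and adjusted p = 0.17 with an estimated correlation), with *CYP81F2* (−2.30 ± 0.31) and *CYP81F4* (−1.49 ± 0.14) lower. Of 4 camalexin genes, 3 were lower, among them *PAD3* (−2.69 ± 0.54), with an adjusted p of 0.0148 with the preset correlation and an adjusted p of 0.356 with an estimated correlation. Photosynthesis genes were lower in 17 of 27 cases and higher in 3 (18 and 3 adjusted over the list alone, median −0.22, adjusted p = 6.17e-06 with the preset correlation and adjusted p = 0.487 with an estimated correlation), such as *PSAF* (−0.49 ± 0.05). Expansion genes were lower in 12 of 19 cases and higher in 3 (13 and 3 adjusted over the list alone, median −0.35, adjusted p = 4.57e-06 with the preset correlation and adjusted p = 0.146 with an estimated correlation), such as *EXPA8* (94.9 ± 5.11 CPM against 189 ± 5.15 in Col-0) and *PIF4* (−0.64 ± 0.04).

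Lists of plant state had more genes lower than higher in cdk8-1. Clock genes were lower in 6 of 9 cases and higher in 1 (7 and 1 adjusted over the list alone, median −0.18, adjusted p = 0.00619 with the preset correlation and adjusted p = 0.0794 with an estimated correlation), such as *PRR9* (−0.57 ± 0.06). Senescence genes were lower in 5 of 11 cases and higher in 2 (5 and 3 adjusted over the list alone, adjusted p = 0.366 with the preset correlation), with *SEN1* lower (−1.71 ± 0.14). Touch genes were lower in 3 of 7 cases and higher in 1 (adjusted p = 0.0563 with the preset correlation), with *TCH3* lower (−1.62 ± 0.13), and heat shock genes were lower in 2 of 4 cases (adjusted p = 0.34 with the preset correlation).

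Other lists went both ways in cdk8-1. The myrosinase gene *TGG2* fell from 2922 ± 151 to 1025 ± 63.8 CPM, while *PYK10* (1.39 ± 0.08) and *NSP1* (1.11 ± 0.05) rose. Among aliphatic glucosinolate genes, 6 of 18 were higher and 10 lower, with the chain elongation genes *MAM3* (0.92 ± 0.09) and *IPMI2* (0.62 ± 0.05) higher and *AOP2* (−0.73 ± 0.07) and *CYP83A1* (−0.66 ± 0.05) lower. In jasmonate synthesis, 2 of 15 genes were higher and 6 lower (4 and 6 adjusted over the list alone), and *LOX4* fell by 1.37 ± 0.13 on the log2 scale, with a list median of 0.02 and mean of −0.16 (adjusted p = 0.249 with the preset correlation). Of the *JAZ* genes, *JAZ1* fell by 0.87 ± 0.13 and *JAZ6* by 0.36 ± 0.08 on the log2 scale, and *JAZ2* rose by 0.25 ± 0.08. The call of *JAZ2* ended without Col-0 replicate 2 (0.23, adjusted p = 0.072, edgeR), without Col-0 replicate 3 (0.18, adjusted p = 0.118, edgeR) and without cdk8-1 replicate 1 (0.24, adjusted p = 0.064, edgeR), and it was lost with DESeq2. The call of *JAZ6* was lost in the 3 tests on TPM values. Reference genes were higher in 2 of 6 cases, *GAPC1* (0.29 ± 0.04) and *EF1A* (0.21 ± 0.05).

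In all, 2226 genes were higher and 2624 lower in cdk8-1 than in Col-0, or 25.4% of those tested, and 189 and 471 changed at least 2-fold. The 3 libraries of each genotype did not overlap for 37.6% of the genes, against 10% by chance. Of the called genes, 45.9% were higher, against 69.4% with TPM values, and no gene called in both changed direction. Among genes with an average log2 CPM of at least 1, the largest falls were those of AT4G01390, a TRAF-like gene (52.3-fold, −5.71 ± 0.25), *ATBETA-AMY*, a beta-amylase gene (−3.97 ± 0.23), the ankyrin repeat gene AT4G03450 (−3.82 ± 0.36), *TPS04* and *CDK8*. The largest rises were those of the lanosterol synthase gene *LAS1* (2.78 ± 0.29), the dirigent-like gene AT3G55230 (2.60 ± 0.18), AT1G11070 (2.51 ± 0.10), AT1G09500 (2.28 ± 0.25) and the aspartyl protease gene AT1G62290 (2.11 ± 0.09).

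The comparison of jazD cdk8-1 with jazD asks which part of the jazD expression state changes when CDK8 is lost. Most of the defence genes that were high in jazD were lower. *VSP2* was at 280.3 ± 27.5 CPM against 1169 ± 28.3 in jazD, *NATA1*, which encodes an acetyltransferase that makes a defence amino acid, fell 23.4-fold to 10.7 ± 1.49 CPM (−4.55 ± 0.14), and *MBP2* (−2.58 ± 0.07), *JAL35* (−2.04 ± 0.05) and *ARGAH2* (−1.59 ± 0.04) fell. Of 18 anti-insect genes, 16 were lower and none higher (median −2.02, adjusted p = 0.00093 with an estimated correlation). In the jasmonate and ethylene branch, 13 of 14 genes were lower (median −2.51, adjusted p = 0.00672 with an estimated correlation). *PDF1.2c* (−6.83 ± 0.24) and *PDF1.2b* (−6.81 ± 0.21) fell 114-fold and 112-fold, *CHIB* fell by 3.70 ± 0.12 on the log2 scale and *PR4* fell 10.6-fold to 164.7 ± 7.48 CPM.

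Indole glucosinolate genes were lower in 14 of 18 cases and higher in 1 (median −0.60, adjusted p = 0.00093 with an estimated correlation). *CYP81F4* fell 9.65-fold to 11.6 ± 1.15 CPM, close to its level of 8.84 ± 1.28 in Col-0. That is still above its 3.54, 2.22 and 3.60 CPM in the cdk8-1 libraries. *MYB51*, the gene of a regulator of the pathway, fell by 2.17 ± 0.12 on the log2 scale, and *GSTF10* fell by 1.91 ± 0.04. Tryptophan genes were lower in 8 of 9 cases (median −0.84, adjusted p = 0.012 with an estimated correlation), such as *TSA1* (−1.05 ± 0.06) and *TSB1* (−1.25 ± 0.05), the latter in the chromosome 5 interval. Of 15 jasmonate synthesis genes, 11 were lower and 1 higher (median −0.47, adjusted p = 0.00275 with an estimated correlation), with *LOX2* down to 2894 ± 37.9 CPM (−0.74 ± 0.05) and *LOX4* by more (−1.97 ± 0.09). Of 11 genes for myrosinases, specifier proteins and ER bodies, 8 were lower and 2 higher (9 and 2 adjusted over the list alone, median −0.36, adjusted p = 0.0332 with an estimated correlation), *NAI2* (−1.15 ± 0.06) and *BGLU18* (−0.59 ± 0.05) among the lower and the myrosinase gene *TGG1* (0.79 ± 0.05) among the higher.

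Aliphatic glucosinolate genes rose when CDK8 was lost in jazD. Of 18 tested, 13 were higher and 1 lower (14 and 1 adjusted over the list alone, median 0.46, adjusted p = 8.67e-12 with the preset correlation and adjusted p = 0.0794 with an estimated correlation). *MAM3* rose 3.18-fold (1.67 ± 0.10), *IPMI2* rose by 0.98 ± 0.05, and the sulfotransferase gene *SOT18* rose by 0.79 ± 0.05. Salicylate genes were lower in 11 of 18 cases (12 adjusted over the list alone, median −0.90, adjusted p = 0.000157 with the preset correlation and adjusted p = 0.452 with an estimated correlation), with *PR1* going from 66.3 ± 34.2 to 4.22 ± 4.30 CPM (−3.94 ± 0.43). All 4 camalexin genes were lower, such as *PAD3* (−3.82 ± 0.34), with an adjusted p of 0.000617 with the preset correlation and an adjusted p of 0.186 with an estimated correlation. Jasmonate signalling genes were lower in 9 of 17 cases and higher in 2 (9 and 3 adjusted over the list alone, adjusted p = 0.00919 with the preset correlation and adjusted p = 0.156 with an estimated correlation), among them *JAO4* (−3.54 ± 0.28) and *CYP94C1* (−1.94 ± 0.17), which inactivate the hormone. Flavonoid genes went both ways, with 4 higher and 9 lower of 19 (adjusted p = 0.181 with the preset correlation): *FLS1* rose 2.00-fold, while *UGT75C1* (−1.14 ± 0.07), *LDOX* (−0.92 ± 0.07) and the regulator gene *MYB113* (−3.18 ± 0.32) fell. The transporter gene *DTX18* fell 28.8-fold to 8.43 ± 0.678 CPM. Of the *JAZ* genes, *JAZ13* (−3.40 ± 0.45), *JAZ8* (−2.62 ± 0.32), *JAZ5* (−2.35 ± 0.32), *JAZ10* (−1.63 ± 0.16), *JAZ6* (−1.27 ± 0.20), *JAZ3* (−0.52 ± 0.07) and *JAZ9* (−0.46 ± 0.05) fell, and the other 5 tested did not pass (*JAZ1*, *JAZ2*, *JAZ4*, *JAZ11* and *JAZ12*). All that fell except *JAZ8* are mutated in both genotypes compared.

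**Figure D3:**
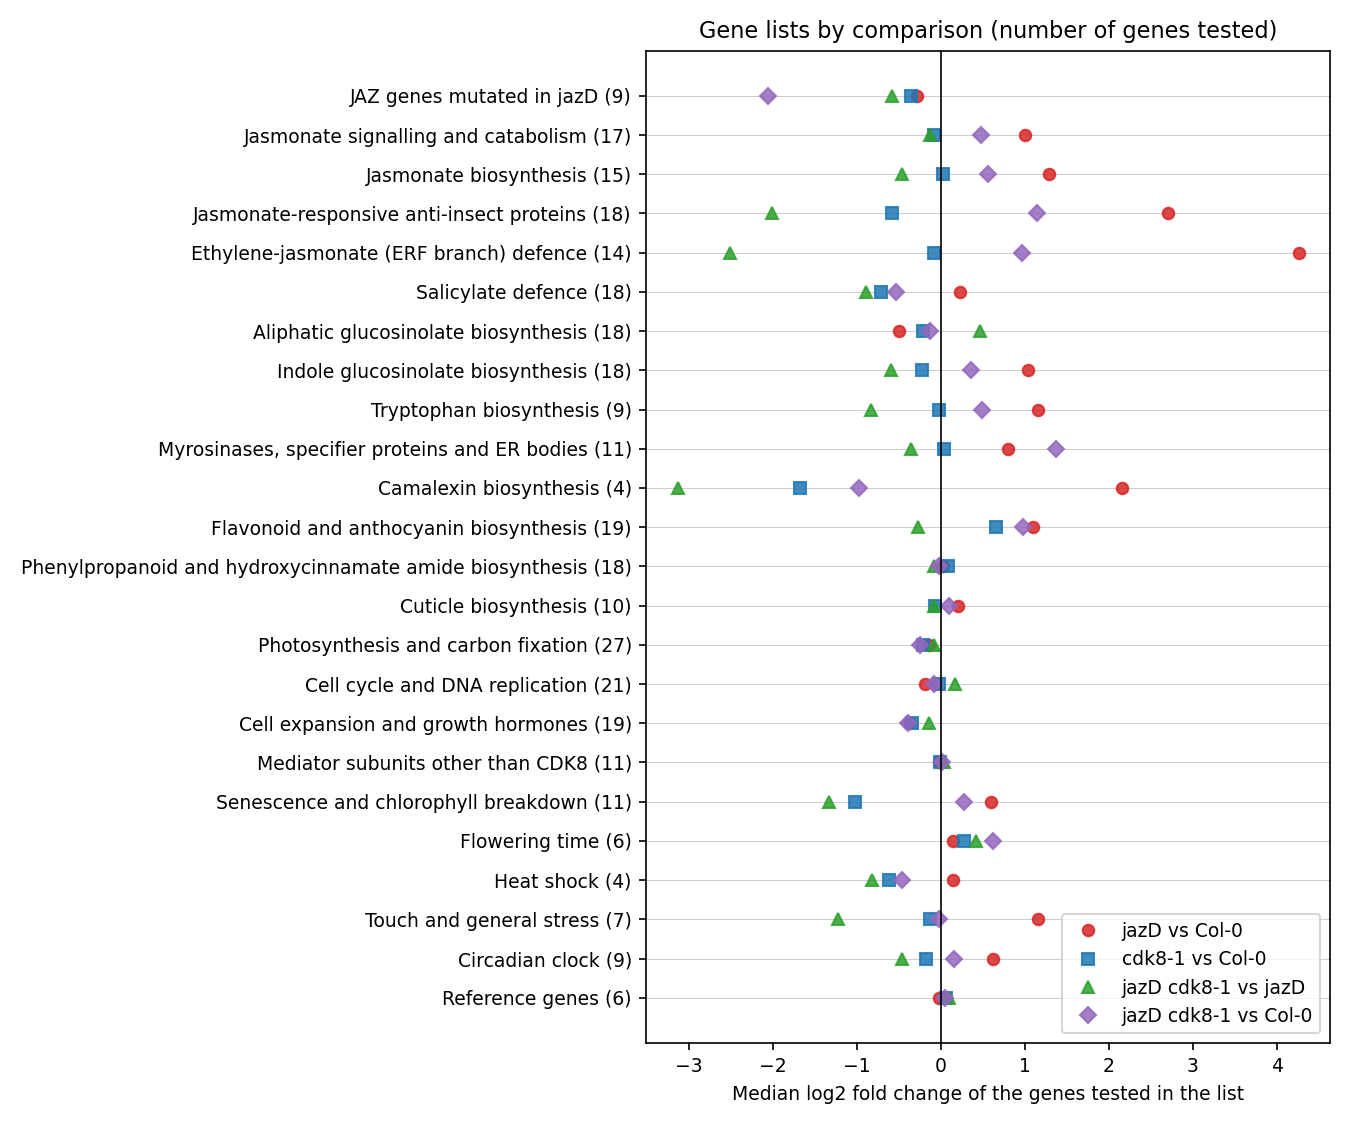
Median log2 fold change of the genes tested in each list (the number tested in parentheses) for 4 comparisons. In the anti-insect list the median is 2.70 in jazD and 1.14 in jazD cdk8-1 against Col-0, and −2.02 in jazD cdk8-1 against jazD. In the aliphatic glucosinolate list it is −0.50, −0.13 and 0.46 in the same order.

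In the touch, senescence and clock lists, more genes were lower than higher in jazD cdk8-1 against jazD, without a list call that held with an estimated correlation. Touch genes were lower in 6 of 7 cases (6 lower and 1 higher adjusted over the list alone, median −1.23, adjusted p = 0.000309 with the preset correlation and adjusted p = 0.182 with an estimated correlation), with *TCH3*, a calmodulin-like gene, at 41.1 ± 3.81 CPM against 166.2 ± 38.8 in jazD. Senescence genes were lower in 7 of 11 cases and higher in 2 (median −1.33, adjusted p = 0.0103 with the preset correlation and adjusted p = 0.311 with an estimated correlation). In the clock list, 5 of 9 genes were lower and 3 higher, such as *ELF4* (−1.88 ± 0.11) and *LUX* (−0.99 ± 0.07), with an adjusted p of 0.00971 with the preset correlation and an adjusted p of 0.0834 with an estimated correlation. Phenylpropanoid genes were lower in 7 of 18 cases and higher in 4 (9 and 5 adjusted over the list alone, adjusted p = 0.0014 with the preset correlation and adjusted p = 0.0637 with an estimated correlation). Photosynthesis genes had 5 higher and 9 lower of 27 (5 and 10 adjusted over the list alone, adjusted p = 0.877 with the preset correlation), so no shift of that list was seen.

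In this comparison 3212 genes were higher and 3613 lower, or 35.8% of those tested, and 298 and 850 changed at least 2-fold. The libraries did not overlap for 47.9% of the genes, against 10% by chance. Of the called genes, 47.1% were higher, against 75.7% with TPM values, which shifted the median of all genes by 0.126 (0.146 with the smaller pseudocount), and no gene called in both changed direction. The largest falls were those of *DIN11*, a gene of the oxygenase family induced by darkness (−7.12 ± 0.19), *PDF1.3* (−7.03 ± 0.36), *PDF1.2c*, *PDF1.2b* and AT4G16260, a beta-glucanase family gene (−6.16 ± 0.16). By the fitted fold, the 5 largest rises were all genes of the chromosome 5 interval: AT5G50565 (0 counts in jazD, at least 148-fold higher), AT5G49440 (9.73 ± 0.20), AT5G45490 (9.19 ± 0.21), AT5G49640 (ratio 406, counting interval 72.6 to 16100) and AT5G50665 (ratio 337, counting interval 60.2 to 13400). With 6 and 5 summed counts in jazD, AT5G49440 and AT5G45490 have folds less certain than their standard errors show.

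What stayed changed in the combined mutant was read from jazD cdk8-1 against Col-0. *VSP2* was still higher than in Col-0 (3.99 ± 0.12), as were *LOX2* (2.36 ± 0.05), *BGLU18* (3.51 ± 0.06) and *PDF1.2a* (3.75 ± 0.41). With an estimated correlation, 5 lists were higher. They were myrosinases and ER bodies (10 of 11 higher and 1 lower, median 1.37, adjusted p = 8.79e-06) and jasmonate synthesis (11 of 15, 12 adjusted over the list alone, adjusted p = 3.51e-05). Flavonoids (17 of 19, median 0.98, adjusted p = 0.00093), jasmonate signalling (13 of 17, adjusted p = 0.00204) and anti-insect proteins (11 of 18 higher and 3 lower, adjusted p = 0.00378) were the others. The mutated *JAZ* genes were lower as a list, in 7 of 9 cases with 1 higher (median −2.06, adjusted p = 0.00223 with an estimated correlation). In the jasmonate and ethylene branch, 8 of 14 genes were higher (adjusted p = 0.000434 with the preset correlation and adjusted p = 0.182 with an estimated correlation). Photosynthesis genes were lower in 21 of 27 cases (22 adjusted over the list alone, median −0.25, adjusted p = 6.4e-08 with the preset correlation and adjusted p = 0.427 with an estimated correlation). In all, 3111 genes were higher and 3064 lower, with 50.4% of calls higher against 66.8% with TPM values. Against cdk8-1, the combined mutant had 2430 genes higher and 2140 lower, and the lists for myrosinases and ER bodies (10 of 11 higher, adjusted p = 7.5e-06), jasmonate synthesis (13 of 15 higher, with 1 lower when adjusted over the list alone, adjusted p = 1.15e-05) and anti-insect proteins (12 of 18 higher, adjusted p = 0.000329) had the smallest adjusted p of the higher lists with an estimated correlation.

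The calls in jazD against Col-0 and in jazD cdk8-1 against jazD were set against each other to count the genes whose jazD change was opposed when CDK8 was lost. Of 4162 genes higher in jazD, 2309 (55.5%) were lower in jazD cdk8-1 than in jazD, where independent lists would share 789. Of 3991 genes lower in jazD, 1959 (49.1%) were higher in jazD cdk8-1 than in jazD, where independent lists would share 672.6. Changes in the same direction were shared by 121 and 256 genes. Both comparisons use the jazD libraries, and simulated data with no effect of *cdk8-1* in jazD gave means of 1.25 and 0.1 genes over 20 simulations. Those data had a mean of 2.4 genes called in jazD cdk8-1 against jazD, so a small overlap followed from their design. They do not show how much of the observed overlap comes from the shared libraries when *cdk8-1* has an effect. Across genes, which are not independent replicates, the 2 sets of fold changes had a correlation of −0.663 and a covariance of −0.302, against −0.128 and −0.018 in the simulations, a difference in covariance of −0.284. The effect of *cdk8-1* itself was shared in part between backgrounds: of 2624 genes lower in cdk8-1 than in Col-0, 1505 (57.4%) were also lower in jazD cdk8-1 than in jazD, where independent lists would share 497.4, and these comparisons share no library. Opposed genes can thus include genes that *cdk8-1* moved the same way without the jazD mutations. Their number is not that of jazD changes that depend on CDK8. Of genes higher in jazD, 830 were lower and 622 higher in cdk8-1 than in Col-0. Of genes lower in jazD, 576 were higher and 892 lower in cdk8-1 than in Col-0.

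The size of the jazD effect was then compared between plants with and without CDK8, in 2 comparisons that share no library. Over the 8153 genes called in jazD against Col-0, the slope of the jazD effect in the cdk8-1 background on that in the background with CDK8 was 0.44, and 88.9% of the genes had the smaller change without CDK8. The slope was 0.505 for genes that rose in jazD and 0.308 for those that fell, and the SD of the slope over 81 draws of 1 library per genotype was 0.042. Genes are not independent replicates, so no p is given. Simulated data with equal effects gave a slope of 0.937 (0.911 to 0.95) and 60.5% of genes smaller, and over all genes a slope of 0.93 (0.907 to 0.945). Over the 4570 genes chosen on the other axis the slope was 0.611, against 0.995 in those simulations, and 52.4% of these genes had the smaller change without CDK8. Over all genes tested that share was 64.4% and the slope was 0.431. Without the chromosome 5 interval, the slope over genes called in jazD against Col-0 was 0.493, against 0.44 with it, and it was 0.519 for genes that rose and 0.409 for those that fell.

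**Figure D4:**
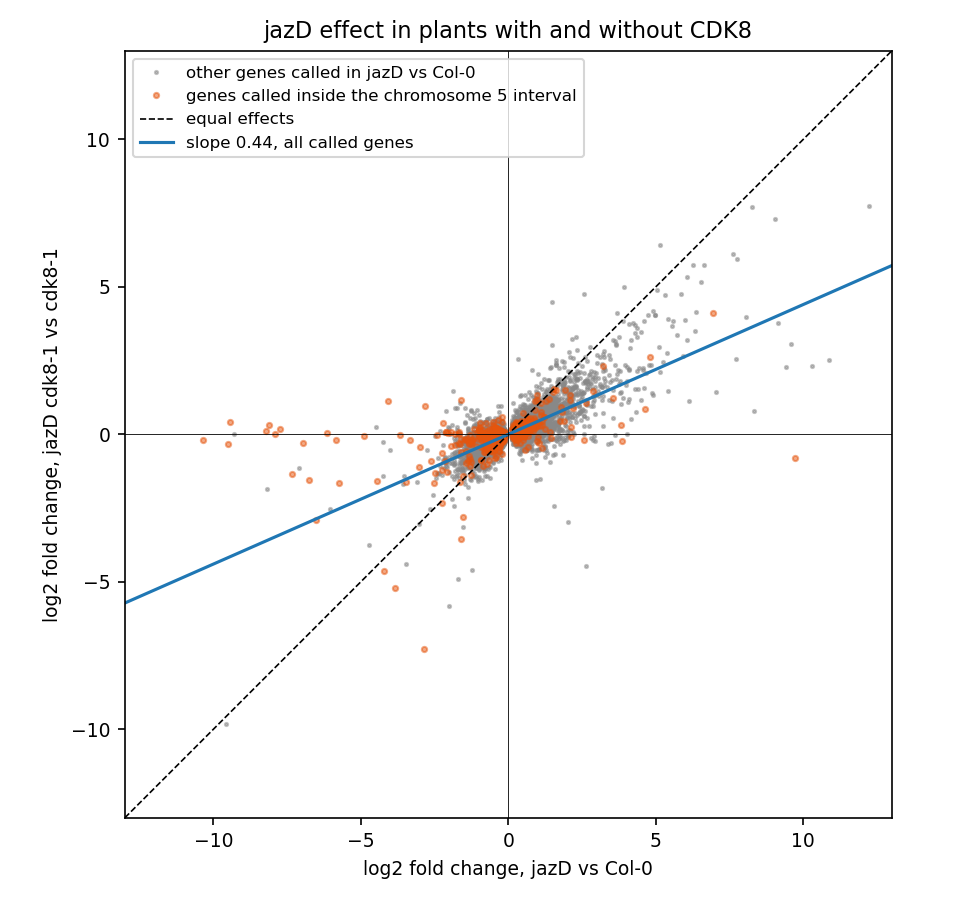
Log2 fold change of jazD cdk8-1 against cdk8-1 (vertical) plotted on that of jazD against Col-0 (horizontal) for the 8153 genes called in jazD against Col-0, 1 point per gene. The fitted line has a slope of 0.44, below the dashed line of equal effects, and genes of the chromosome 5 interval are in orange.

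The interaction term tests for each gene whether the effect of *cdk8-1* differs between jazD and the background with intact *JAZ* genes. For tryptophan synthesis, 8 of 9 genes had a more negative *cdk8-1* effect in jazD (median −0.75, adjusted p = 0.00599 with an estimated correlation), led by *TSA1* (−1.26 ± 0.09) and by *TSB1* (−1.27 ± 0.07) of the chromosome 5 interval. For indole glucosinolates, 11 of 18 were more negative and 2 more positive (12 and 2 adjusted over the list alone, median −0.49, adjusted p = 0.00275 with an estimated correlation), such as *GSTF10* (−1.43 ± 0.06) and *IGMT5* (−2.20 ± 0.20). Flavonoid genes were more negative in 12 of 19 cases and more positive in 1 (12 and 2 adjusted over the list alone, median −0.73, adjusted p = 0.00281 with an estimated correlation). Among them *CHS* (−1.23 ± 0.07) and *LDOX* (−1.57 ± 0.13) rose with *cdk8-1* in the presence of JAZ repressors and fell with it in jazD. Aliphatic glucosinolate genes were more positive in 16 of 18 cases (17 adjusted over the list alone, median 0.44, adjusted p = 0.0273 with an estimated correlation), such as *CYP79F1* (0.92 ± 0.07) and *AOP2* (1.18 ± 0.11).

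Jasmonate synthesis genes had a more negative effect of *cdk8-1* in jazD in 8 of 15 cases (10 adjusted over the list alone, median −0.30, adjusted p = 0.00599 with an estimated correlation), such as *AOC2* (−0.73 ± 0.07). The same was found for anti-insect genes in 9 of 18 cases (median −0.51, adjusted p = 0.0295 with an estimated correlation), such as *ARGAH2* (−1.61 ± 0.06) and *JAL35* (−1.67 ± 0.08). Of genes for myrosinases and ER bodies, 5 of 11 were more negative and 3 more positive (median −0.18, adjusted p = 0.013 with an estimated correlation), with *PYK10* (−1.91 ± 0.10) and *TGG2* (1.38 ± 0.08) on opposite sides. In the jasmonate and ethylene branch, 10 of 14 genes were more negative (11 adjusted over the list alone, median −1.81, adjusted p = 4.86e-08 with the preset correlation and adjusted p = 0.0637 with an estimated correlation), such as *CHIB* (−2.39 ± 0.26). Without cdk8-1 replicate 3, at least 3 of these calls were lost: *PDF1.3* (−3.22, adjusted p = 0.493, edgeR), *PDF1.2c* (−4.72, adjusted p = 0.0577, edgeR) and *PDF1.2b* (−3.16, adjusted p = 0.384, edgeR). For *CDK8* itself the interaction was 0.16 ± 0.16 (adjusted p = 0.556, edgeR). Among the *JAZ* genes it was negative for *JAZ10* (−1.58 ± 0.28), *JAZ5* (−1.75 ± 0.41), *JAZ6* (−0.91 ± 0.22), *JAZ9* (−0.51 ± 0.07), *JAZ3* (−0.41 ± 0.09) and *JAZ8* (−2.75 ± 0.81), and positive for *JAZ1* (0.86 ± 0.23). Except for *JAZ8*, these genes are mutated in jazD, so transcripts of mutated and intact genes are compared and regulation through CDK8 is not isolated. The call of *JAZ1* ended without jazD cdk8-1 replicate 2 (0.68, adjusted p = 0.069, edgeR), and that of *JAZ8* without cdk8-1 replicate 2 (−2.79, adjusted p = 0.0509, edgeR) or cdk8-1 replicate 3 (−2.63, adjusted p = 0.0803, edgeR). Those of *JAZ5* and *JAZ6* were lost in the test on TPM values without a filter. No camalexin gene passed (0 of 4, adjusted p = 0.121 with the preset correlation), so the difference between backgrounds was not shown for that list. The gene *TPS04* was at 9.24 ± 1.27 CPM in jazD and 1.47 ± 1.06 in jazD cdk8-1, a fall close to that seen without the jazD mutations.

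The interaction passed for 3154 genes (16.5%), of which 1555 were more positive and 1599 more negative in jazD, and 161 and 292 differed at least 2-fold. Of these calls 49.3% were more positive, against 59.7% with TPM values. Inside the chromosome 5 interval, 54.5% of genes were called in jazD against Col-0, and 42.2% outside it. The interaction passed for 28.9% of genes inside the interval and 15.9% outside it. The 5 most positive were genes of the chromosome 5 interval, AT5G50565 (10.19 ± 0.47), AT5G45490 (9.83 ± 0.24), AT5G49440 (9.16 ± 0.25), AT5G49640 (8.34 ± 0.39) and AT5G51630 (7.95 ± 0.44). AT5G50565, AT5G49640 and AT5G51630 had at most 1 count in jazD, so these fitted values depend on the prior count and are not bounds. AT5G45490 and AT5G49440 had 5 and 6 summed counts in jazD, so their values are less certain than the standard errors show. The 5 most negative were *PDF1.3* (−8.34 ± 1.04), *PDF1.2c* (−7.98 ± 0.96), *PDF1.2b* (−7.14 ± 0.97), *AACT1* (AT5G61160, −6.52 ± 1.05) and *DIN11* (−5.61 ± 0.89). The values of the first 4 rested on cdk8-1 replicate 3, where *PDF1.2a* was at 10.2 CPM against 0.249 and 0.414 CPM in the other libraries of that genotype. Without that library they were −3.22 (adjusted p = 0.493), −4.72 (adjusted p = 0.0577), −3.16 (adjusted p = 0.384) and 0.32 (adjusted p = 0.804) in edgeR. The *PDF1.2b* call was also lost in 2 of the 3 tests on TPM values.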

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

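The scan of chromosome 5, its runs by either rule and the search of the interval for mutated *JAZ* genes were chosen only after the result was seen. The slope on the other axis was set before the data were examined, and its use as a test of regression to the mean was chosen afterwards.

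The interaction is a planned test of the difference between the 2 backgrounds. The effect of *cdk8-1* differed between jazD and the background with intact *JAZ* genes for 3154 genes. With the labels of *cdk8-1* redrawn within each background, 1 of 100 groupings, the real one, reached that count, and the highest of the others was 2530. Redrawn labels stand for no *cdk8-1* effect in either background, not for equal effects in both. A grouping close to the real one in only 1 of the backgrounds can turn that effect into interaction calls. The share therefore does not test whether the effects differ. Among the genes named by rule, the most positive differences were those of AT5G50565 (10.19), AT5G45490 (9.83), AT5G49440 (9.16), AT5G49640 (8.34) and AT5G51630 (7.95). The most negative were those of *PDF1.3* (−8.34), *PDF1.2c* (−7.98), *PDF1.2b* (−7.14), *AACT1* (AT5G61160, −6.52) and *DIN11* (−5.61). Among lists, the median difference was −0.30 for jasmonate biosynthesis, −0.51 for anti-insect proteins, 0.44 for aliphatic glucosinolates, −0.49 for indole glucosinolates, −0.75 for tryptophan biosynthesis, −0.18 for myrosinases and ER bodies and −0.73 for flavonoids.

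The number of list calls over all comparisons, 77, is not a test of that difference. With genotype labels redrawn over all 12 libraries, it was reached in 5 of 100 groupings including the real one, with 82 as the highest other, so chance was not excluded for that number. Such groupings still hold part of the real differences between libraries, so they do not show what unrelated libraries would give.

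The 5 most positive differences all lie in 1 interval of chromosome 5, where genes near 0 in jazD sit together (permutation p = 1e-04 for the clustering). A change at a mutated *JAZ* gene is argued against by the 0 such genes inside the interval. Regulation of each gene on its own through CDK8 stays open. Few runs of levels in jazD cdk8-1 were seen with 3 levels (permutation p = 4e-04), by a rule chosen after the values were seen. That rule also places *AtPP2-A6* on its few counts. Runs with the nearer of 2 (permutation p = 0.261) cannot decide, since they place AT5G44530 on a near tie and *AtPP2-A6* by a fitted fold from 0 counts. The pattern is consistent with a strain variant in the jazD line, carried by a chromosome segment, and expression of genes in the interval, *TSB1* among them, could differ for that reason alone. A return of Col-0 sequence with *cdk8-1*, farther along the chromosome, may explain most levels in jazD cdk8-1. A single returned segment does not predict that *TRM24* (−3.61 against Col-0) and AT5G52940 (−4.36) stay low between genes that do not. The level of *AtPP2-A6* (−2.71 against Col-0) is not settled at its few counts. All of these remain hypotheses that DNA variants in the jazD and jazD cdk8-1 lines would decide, and these were not analysed here. Loci at or near 0 in mutant lines also occurred outside the interval. Summed counts of AT5G32950 were 238 in Col-0 and 0 in cdk8-1, jazD and jazD cdk8-1. Those of AT4G08093 were 108 in Col-0 and 1, 0 and 0 in the same order. Whether such differences from Col-0 belong to the lines or to the named mutations was not tested.

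The smaller jazD effect without CDK8 had a slope of 0.44, where simulated equal effects gave 0.911 to 0.95, and 0.418 to 0.487 with 1 library left out. Regression to the mean is argued against by the slope of 0.611 over genes chosen on the other axis, where simulated equal effects gave 0.995, and the interval by the slope of 0.493 over genes called in jazD against Col-0 outside it. The share of genes with the smaller change without CDK8 was 88.9% of those called in jazD against Col-0 and 52.4% of those chosen on the other axis. With labels redrawn within backgrounds, 7 of 100 groupings including the real one lay as far from a slope of 1 as the observed 0.56, and the farthest lay 0.728 away. That test did not exclude chance, though its groups mix libraries with and without CDK8 and so carry real differences, with slopes from 0.272 to 1.087.

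The 4 defensin and *AACT1* differences rest on cdk8-1 replicate 3. Without it *AACT1* (AT5G61160) was 0.32, on the other side of 0, and *PDF1.3* was −3.22. The close copy *PDF1.2a* had 212 counts in that library against 5 and 8 in the other cdk8-1 libraries, and 109, 84 and 33 in Col-0. Whether the *cdk8-1* effect on these genes differs between backgrounds stays open.

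For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real grouping alone, 1 of 10, gave the real count in each: 8153 in jazD against Col-0 (highest other 0), 4850 in cdk8-1 against Col-0 (1), 6825 in jazD cdk8-1 against jazD (1), 6175 in jazD cdk8-1 against Col-0 (0), 4570 in jazD cdk8-1 against cdk8-1 (2), and 4268 opposed genes (0).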

How the results depend on the processing

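Counts of calls moved by more than 1.5 times with a fold threshold, with a stricter adjusted p and, in some comparisons, with limma on log2 TPM, which changes both the values and the test. The cause was not tested unless stated. With at least 2-fold required, the calls higher and lower were 817 and 435 (jazD against Col-0), 189 and 471 (cdk8-1 against Col-0), 298 and 850 (jazD cdk8-1 against jazD), 369 and 521 (jazD cdk8-1 against Col-0), 381 and 164 (jazD cdk8-1 against cdk8-1), and 161 and 292 (interaction), fewer by construction. Opposed genes numbered 490 and 136 with that requirement. At an adjusted p of 0.01, 1310 genes were higher in cdk8-1, 2118 higher in jazD cdk8-1 than in jazD, 1589 and 1293 higher and lower in jazD cdk8-1 than in cdk8-1, and 849 and 890 in the interaction. With limma on log2 TPM (pseudocount 1, pseudocount 0.1, and pseudocount 1 without a filter), genes higher in cdk8-1 were 3947, 3913 and 3667, and genes lower were 1739 (pseudocount 1) and 1688 (no filter). In jazD cdk8-1 against jazD they were 6475, 6499 and 6206 higher and 2075, 2048 and 2117 lower. Genes lower in the interaction were 1056 (pseudocount 0.1) and 968 (no filter). List calls numbered 38 with an estimated correlation, against 77.

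The slope of the jazD effect was 0.611 with genes chosen on the other axis, and 0.493 without the chromosome 5 interval, an alternative chosen after seeing the data. With 1 library left out it ranged from 0.418 (without jazD replicate 3) to 0.487 (without cdk8-1 replicate 3). For AACT1 (AT5G61160), interaction values ranged from −7.22 (without Col-0 replicate 2) to 0.32 (without cdk8-1 replicate 3). Leaving out 1 library gave 3733 to 4241 genes higher and 3375 to 4113 lower in jazD, and 1182 to 1499 and 1273 to 1598 in the interaction.

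Replicate numbers do not pair the samples: of 18 same-numbered pairs, 0 had a correlation over 0.1. With the number as a replicate block, 4068 genes were higher and 3867 lower in jazD, 2118 and 2560 in cdk8-1, and list calls again numbered 77, with 1 lost and 1 gained.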

Other observations

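The family scan and the contrast of morning with later clock genes were chosen only after the results were seen.

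Mannose-binding lectins of the jacalin type were the only gene family past 0.05 with an estimated correlation, in 1 of 708 tests (177 families in 4 comparisons), with an adjusted p of 0.0104 in jazD against Col-0. Of 12 genes tested, 6 were higher and 4 lower, with a median of 1.63. *JAL33* (3.99), *JAL34* (3.95), AT1G52000 (3.68), AT1G52100 (3.62), *JAL35* (3.45) and AT5G38550 (3.17) rose, while *RTM1* (−0.52), AT1G05770 (−1.34), AT1G19715 (−0.46) and AT1G73040 (−1.20) fell. Lectins of this type bind sugars. The family test passed although 4 of its genes fell, so the rise was not shared by all members. With the preset correlation 37 of the 708 tests passed.

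Clock genes showed a shift between phases in jazD: the median of later genes minus that of morning genes was 2.9, from −1.58 for morning genes and 1.32 for later ones. Morning genes were *CCA1*, *LHY* and *PRR9*, and later genes were *PRR5*, *TOC1*, *ELF4*, *LUX* and *GI*. *PRR7* of the clock list was in neither group. The same difference of medians was −0.47 in cdk8-1 against Col-0, 1.62 in jazD cdk8-1 against Col-0 and −1.37 in jazD cdk8-1 against jazD. A later harvest of the jazD plants could produce such a shift, and it cannot be told apart from a change of the clock in that genotype, since the hour of harvest is not given in the sources used here. Sampling each genotype at several known hours would separate these. A difference in harvest hour would follow genotype in every comparison, so it could add to calls of other genes and lists too. That was not tested.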
